A study of Homo sapiens with 4 samples.

How the data were processed

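The series holds 4 libraries of poly(A) RNA from 5-fluorouracil-resistant HCT-8 cells treated with cycloheximide, 2 with a METTL14 plasmid and 2 with a control plasmid, and groups and replicate numbers were taken from the labels. Per the labels' protocols, RNA was extracted with Trizol, fragmented, made into libraries with a NEBNext Ultra kit and sequenced on an Illumina NovaSeq. Per the submitters' processing notes, the tools were fastp, Bowtie2, HISAT2, StringTie and RSEM, with no versions, and the build was hg18. Most gene identifiers of the files (20171 of 20323) are also in GENCODE release 29, an annotation of GRCh38, so the build behind the counts remains unclear, and the coordinates given are those of GENCODE on GRCh38, used for position, transcript length, GC content and exon overlap only. The strand setting of the counting is not given in the sources used here.

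The deposited values are expected counts per gene, estimated by the authors and not normalized (10.8 to 11.6% of the values in a library are not exactly whole, with a tolerance of 0), and they were rounded to whole numbers. Of the gene rows, 4239 were at 0 in each library and 102 had no symbol and took at most 0.037% of counts. Some symbols belong to several rows (965 rows in all). Gene lists then used the named row with the highest mean count, a choice made after the files were seen. RSEM divides reads between overlapping or similar genes, so values of such genes are less certain. Shared exons are pointed out below for some genes only, and further named list members have them too, such as HSP90AA1 with WDR20.

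Counts were analysed in edgeR 4.0.16 (R 4.3.3) with filterByExpr (minimum count 10), TMM normalization and the robust quasi-likelihood test with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over 12700 genes at a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the square root of F and are approximate. The common biological coefficient of variation was 10.8%. With 2 libraries per group an exact permutation test cannot go below the share of 33.3% given for chance separation, so each p-value rests on the model's spread shared over genes. The 2 METTL14 libraries lay closer to each other (chi-square per degree of freedom 3.35) than the 2 controls (29.92), and they still differed by more than sampling noise and were counted as 2. That difference does not show that they come from separate cultures. If they do not, the p-values are too small. Gene lists (38, of which 34 had at least 5 tested members) and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, then with an estimated correlation and with fry.

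Genes named are METTL14 and, among genes with a symbol, an adjusted p below 0.05, a mean of at least 1 CPM and both METTL14 libraries on the same side of both controls, the 12 largest rises and 12 largest falls, skipping unnamed loci. The up to 4 members with the smallest p could be named in each list, and all m6A writers. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here.

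The procedure was tested on simulated counts with 200 changed genes for the comparison of METTL14 overexpression with control. It recovered 50% of those changed 1.5-fold, 84% at 2-fold, 94% at 4-fold and 100% at 8-fold. Of its 188 calls 24 were on unchanged genes, so more than the nominal share of calls can be false. The simulation changed 200 of 12563 genes, a far smaller share than was called in the data, so the false share there may differ. Alternatives were DESeq2 1.42.0 and its size factors, limma-voom, no filter, a filter of 5 CPM in 2 libraries, no robust step, replicate number as a term, glmTreat against 1.5-fold and leaving out each library. Chosen after seeing the data were removal of a trend on length and GC (loess on 12653 genes), library totals with no normalization, and leaving out mitochondrial genes. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.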

Results

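Messenger RNA was measured by poly(A) RNA sequencing in a 5-fluorouracil-resistant derivative of HCT-8, a human colorectal cancer cell line. METTL14, the partner of METTL3 in the enzyme complex that places N6-methyladenosine (m6A) on mRNA, was raised from a plasmid in 2 libraries (METTL14 overexpression, replicates 1 and 2), and a negative control plasmid was used in 2 (control, replicates 1 and 2). The cells of both groups received cycloheximide, a blocker of translation elongation, at 100 ug/mL, so that no value here comes from cells without it. The series describes the work as repeated in independent experiments. Total counts were 20161082 and 19247784 in the controls and 19206661 and 19829158 with METTL14, over 20323 gene rows, and between 14407 and 14890 rows had a count in a library.

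The comparison asks how mRNA levels differ between cells with the METTL14 plasmid and cells with the control plasmid in the drug-resistant line. The METTL14 transcript itself (ENSG00000145388, protein-coding, GRCh38 chromosome 4, 118685368 to 118715433, plus strand) had 472 and 598 counts in the controls and 7593 and 8516 counts with the plasmid. This is 27.6 ± 4.34 against 405.4 ± 21.7 CPM (counts scaled to library size; SD, n = 2), 14.7-fold higher (log2 fold change 3.88, SE 0.141, edgeR adjusted p = 7.32e-05). Of the other 8 m6A writer genes, 4 were lower: ZC3H13 (log2 fold change -1.13, SE 0.124), METTL3, the catalytic subunit (-0.78, SE 0.111), WTAP (-0.62, SE 0.0943) and METTL16 (-0.41, SE 0.132, adjusted p = 0.0335). The METTL16 call was lost when either overexpression library was left out. RBM15 (0.28), RBM15B (0.24), VIRMA (-0.07) and CBLL1 (0.03) did not pass the test. METTL3, WTAP and RBM15B share exon sequence with the genes TOX4, SOD2 and DCAF1, which leaves their counts less certain. As a list the writers were not called (camera adjusted p = 0.707, and adjusted p = 0.764 with an estimated correlation), and the signs of their median (-0.07) and mean (0.16) differ. Adjusted over the list alone, 1 was higher and 4 were lower.

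**Figure D1:**
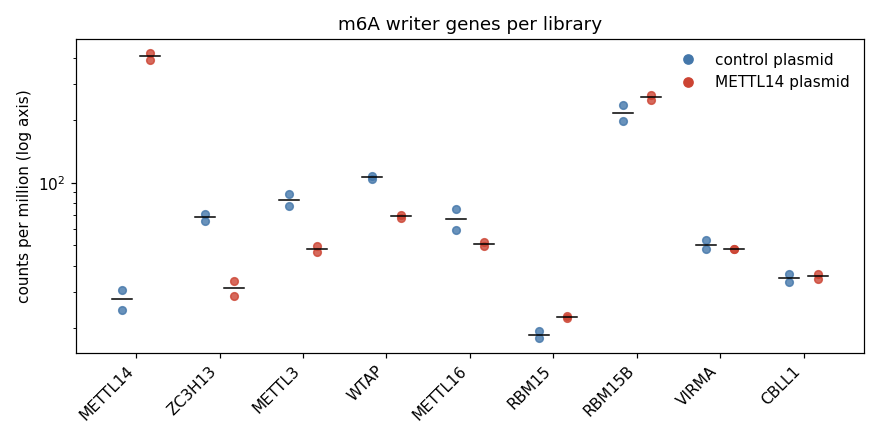
CPM of the 9 m6A writer genes on a log axis, 1 point per library, with a bar at the mean of each group of 2 libraries. METTL14 lies at 24.55 and 30.69 in the controls and at 390.1 and 420.7 with the plasmid, and ZC3H13 falls from 68.18 to 31.23 on average.

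Across the transcriptome, SLC6A12, a betaine transporter, rose from 3.89 ± 1.31 to 307 ± 2.97 CPM (SD, n = 2; log2 fold change 6.30, SE 0.205, edgeR adjusted p = 7.26e-05). FAM111B fell from 13.2 ± 1.33 to 0.861 ± 0.309 CPM (log2 fold change -3.94, SE 0.274) and CCNE2, a cyclin of entry into S phase, from 21.3 ± 4.26 to 2.52 ± 0.215 CPM (-3.08, SE 0.213). In all, 3429 of 12700 tested genes were higher and 3569 lower with METTL14 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), or 55.1% of those tested. The change was at least 2-fold for 1295 of the higher and 1118 of the lower genes. Asked instead for a change beyond 1.5-fold, the test called 1416 higher and 1357 lower. The libraries of the 2 groups did not overlap for 10131 genes (79.8%), where chance gives 33.3%. Leaving out METTL14 overexpression replicate 1 lowered the number of lower genes to 2305.

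**Figure D2:**
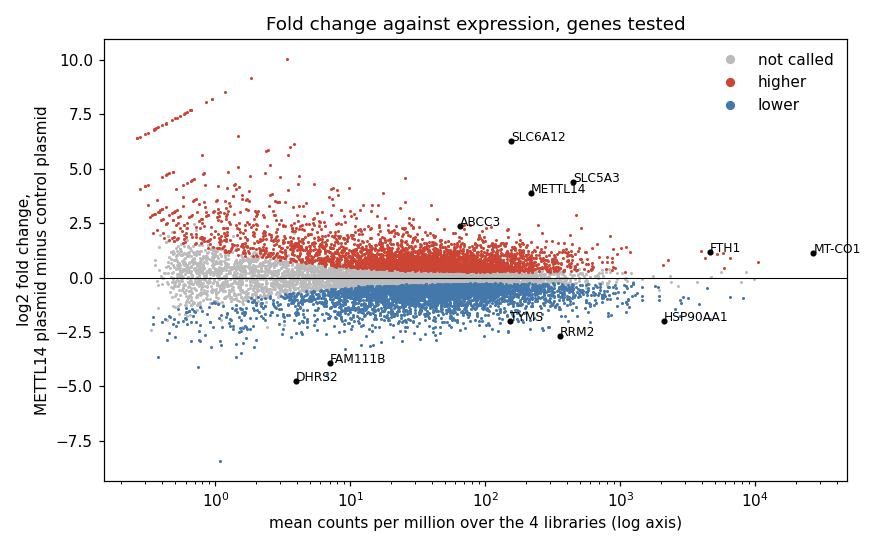
Log2 fold change of each of the 12700 tested genes (METTL14 plasmid minus control plasmid) against its mean CPM over 4 libraries on a log axis, with the 3429 higher and 3569 lower genes in colour. METTL14 (3.88) and SLC6A12 (6.30) stand above genes of similar level, and diagonal rows of points at the left are genes with few counts in 1 group.

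Besides SLC6A12, the largest rises among named genes were in genes almost silent in the controls. CYP24A1, the vitamin D 24-hydroxylase, rose from 0.103 ± 0.000987 to 7.04 ± 1.09 CPM (log2 fold change 6.01, SE 0.408). GBP2, an interferon-inducible GTPase, rose from 0.129 ± 0.108 to 6.81 ± 0.758 CPM (5.65, SE 0.453), and TMIGD3 (6.12, SE 0.42) and CDHR2 (4.81, SE 0.528) rose as well. The controls held only 2 and 2 counts of CYP24A1, 1 and 4 of GBP2, 3 and 1 of TMIGD3 and 1 and 5 of CDHR2. The sizes of these rises are therefore uncertain. Where the controls held 1 to 3 counts in all, the ratio of counts was 113 for ENOX1 (95% exact interval 19.9 to 4500), 62.4 for TMEM59L (21.0 to 305), 60.4 for LEMD1 (20.4 to 296), 37.0 for TRIM31 (12.4 to 182) and 30.9 for ZNF844 (10.2 to 152). UTP14C had no count in either control and 11 and 136 counts with METTL14, at least 47.8-fold higher against a floor of 3 counts over the group. Replicate 2 carries this bound, which is 7.29-fold without it, and the gene's call was lost without control replicate 1 and without a filter on low counts. CDRT4 had 0 and 5 counts against 171 and 22, and its call was lost with limma-voom, without the filter, with replicate number as a term in the model, and without control replicate 1. UTP14C, TMIGD3, TMEM59L, LEMD1, GBP2, CDRT4 and CDHR2 share exon sequence with another gene of the files. These intervals and floors cover counting error only.

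Among the largest falls, ACTL8 had 55 and 29 counts in the controls and none with METTL14, at least 28.7-fold lower against the same floor. DHRS2 fell from 7.62 ± 0.767 to 0.279 ± 0.115 CPM (log2 fold change -4.75, SE 0.352) and CENPE, a kinetochore motor of mitosis, from 16.5 ± 3.6 to 1.68 ± 0.274 CPM (-3.29, SE 0.247). CHML (-3.08, SE 0.16), CAVIN2 (-3.18, SE 0.387), KBTBD8 (-3.08, SE 0.633), KIF17 (-3.65, SE 0.715) and ANXA8 (-3.46, SE 0.623) fell too, and CHML and CCNE2 share exon sequence with OPN3 and INTS8. KBTBD8 had 38 and 38 counts in the controls against 1 and 8, KIF17 73 and 28 against 6 and 2, and ANXA8 76 and 34 against 7 and 3. The sizes of these falls are thus uncertain. The controls differed widely for ANKRD1 (382 and 109 counts, against 7 and 16) and ALPP (767 and 194 counts, against 56 and 56). The calls of both (log2 fold changes -4.44 and -3.14) were lost when either METTL14 library was left out, and that of ALPP also with limma-voom, without the filter and with replicate number as a term.

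Genes of DNA synthesis and cell division were lower with METTL14. Of 40 S phase genes 39 were lower, among them CDC6, which loads the replicative helicase (log2 fold change -2.09, SE 0.106), MCM4 (-2.29, SE 0.137), GINS2 (-2.54, SE 0.167) and FEN1 (-1.95, SE 0.128). Of 38 genes of G2 and mitosis 37 were lower, such as HMMR (-2.86, SE 0.116), CCNB1, cyclin B1 (-1.96, SE 0.0976), ANLN (-2.16, SE 0.117) and DLGAP5 (-2.34, SE 0.127). Of 35 DNA repair genes 30 were lower, with BRCA1 at -2.23 (SE 0.117), RAD51AP1 at -1.99 (SE 0.126) and FANCI at -1.43 (SE 0.0951). Camera adjusted p-values were 2.11e-13 for the S phase list, 3.59e-14 for the G2 and mitosis list and 9.81e-10 for the repair list. These assume a correlation of 0.01 between the genes of a list, where the estimates were 0.764, 0.0411 and 0.101. Each estimate lies above 0.01, that for S phase far above, so these p-values are likely too small, above all that of the S phase list. Such estimates rest on 2 residual degrees of freedom. With an estimated correlation no list of any kind was called: adjusted p = 0.523 with an estimated correlation for the S phase and repair lists, and 0.465 for the G2 and mitosis list. The counts adjusted over the list alone were the same 39, 37 and 30. A list planted in simulated libraries of this design, shifted 1.5-fold, was missed by that version of the test too (adjusted p = 0.188) and found by fry (adjusted p = 0.0428). Its genes were drawn independently of each other. The simulation therefore cannot tell whether correlated lists such as S phase were missed or properly corrected.

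The list of fluoropyrimidine and folate metabolism, which holds the target of 5-fluorouracil and the enzymes that activate and degrade it, was lower (camera adjusted p = 0.000784, and adjusted p = 0.533 with an estimated correlation). The estimate was 0.349, above the preset value. Of its 28 tested genes 18 were lower, 3 higher and 7 not called, and adjusted over the list alone 19 were lower and 3 higher. RRM2, a subunit of ribonucleotide reductase, fell from 619.5 ± 171 to 95.81 ± 2.33 CPM (log2 fold change -2.69, SE 0.188), TK1, thymidine kinase, from 247.4 ± 43.8 to 45.38 ± 1.79 CPM (-2.45, SE 0.143), and NME1 from 208.3 ± 30.7 to 38.43 ± 0.432 CPM (-2.44, SE 0.13). NME1 shares exon sequence with NME1-NME2, which leaves its counts less certain. Named after its values were seen, TYMS, thymidylate synthase and the target of the drug, fell from 245.1 ± 51.2 to 60.71 ± 0.683 CPM (-2.01, SE 0.152). The higher genes included DPYD, which degrades the drug (2.02, edgeR adjusted p = 0.00671), and CDA (0.95, edgeR adjusted p = 0.000778), also named after their values were seen. DPYD has the larger p for the larger change, so its value is less precise.

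Drug efflux transporters were higher as a list (camera adjusted p = 0.0147, and adjusted p = 0.523 with an estimated correlation): 7 of 12 were higher, none was lower and 5 were not called, with the same 7 adjusted over the list alone. ABCC3 rose from 21.26 ± 0.459 to 108.4 ± 2.72 CPM (log2 fold change 2.35, SE 0.103), ABCA3 from 89.41 ± 0.744 to 263.2 ± 9.85 CPM (1.56, SE 0.097), ABCA2 from 115.1 ± 11 to 243.4 ± 11.3 CPM (1.08, SE 0.11) and ABCC5 from 58.42 ± 3.97 to 107.2 ± 0.651 CPM (0.88, SE 0.1). The list's call was lost without control replicate 2 (adjusted p = 0.0603) and with the trend on transcript length and GC content removed (0.113). Targets of NRF2, the regulator of antioxidant genes, were higher (19 of 26, 2 lower, camera adjusted p = 0.000183, and adjusted p = 0.518 with an estimated correlation), with AKR1B10 at 1.78 (SE 0.138), FTH1, ferritin heavy chain, at 1.20 (SE 0.0944) and ME1 at 1.07 (SE 0.101). ABCC3 and ABCC2 are in both of these lists. Adjusted over the list alone, the same 19 and 2 NRF2 targets were called.

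**Figure D3:**
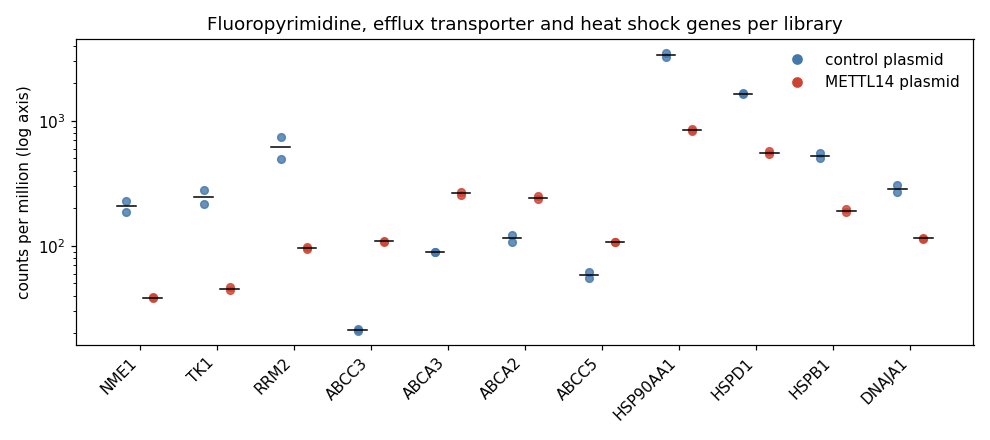
CPM per library (log axis, bar at the group mean) of 3 genes of the fluoropyrimidine list and the 4 genes with the smallest p in each of the efflux transporter and heat shock lists. RRM2 falls from 619.5 to 95.81 and HSP90AA1 from 3369 to 844 on average, and ABCC3 rises from 21.26 to 108.4.

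The lists of ribosomal proteins, rRNA processing, translation factors, the proteasome and heat shock were lower. Of 79 ribosomal protein genes 74 were lower and none higher, with RPSA at -1.37 (SE 0.102) and RPS2 at -1.02 (SE 0.0953), and these genes took 4.85 and 5.38% of counts in the controls and 3.42 and 3.52% with METTL14. Of 32 rRNA processing genes 30 were lower, such as NCL, nucleolin (-1.73, SE 0.0964), and NOP58 (-2.06, SE 0.121), and of 46 translation factors 26 were lower and 2 higher, with EIF5A at -1.60 (SE 0.137). All 31 proteasome genes were lower, with PSMC3 at -1.29 (SE 0.0993), and 16 of 20 heat shock genes, with HSP90AA1 falling from 3369 ± 187 to 844 ± 18.7 CPM (3.99-fold lower) and HSPD1 at -1.57 (SE 0.0962). Camera adjusted p-values were 4.47e-13 for ribosomal proteins, 7.26e-09 for rRNA processing, 1.85e-05 for translation factors, 1.91e-09 for the proteasome and 7.22e-06 for heat shock. With an estimated correlation the adjusted p was 0.465 for the proteasome and 0.523 for the other 4 lists. The estimates were 0.188 for ribosomal proteins, 0.497 for rRNA processing, 0.27 for translation factors, -0.0144 for the proteasome and 0.171 for heat shock. All but that of the proteasome lie above the preset 0.01, so the p-values of the other 4 lists are likely too small. Adjusted over the list alone, 77 ribosomal protein genes were lower and the counts of the other 4 lists were the same. Transcripts of the 2 genomes of the respiratory chain moved apart: 52 of 65 nuclear genes were lower and none higher (NDUFB2 -1.29, SE 0.114, and CYCS, cytochrome c, -1.19, SE 0.112), and 7 of 13 mitochondrial genes were higher and none lower (MT-CO1 1.11, SE 0.0869, and MT-ND5 1.21, SE 0.137). Camera adjusted p was 9.73e-10 for the nuclear and 0.0215 for the mitochondrial list, and adjusted p = 0.523 with an estimated correlation for both. The estimates, 0.122 and 0.242, lie above the preset value too. Adjusted over the list alone, 53 nuclear genes were lower, and 9 mitochondrial genes were higher and 1 lower. Mitochondrial transcripts took 5.99 and 6.26% of counts in the controls and 9.85 and 10.25% with METTL14, and their list lost its call without control replicate 2 (adjusted p = 0.0657) and without METTL14 overexpression replicate 2 (0.0573).

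Targets of Wnt signalling were higher (11 of 21, 2 lower, camera adjusted p = 0.0287, and adjusted p = 0.523 with an estimated correlation), with SOX9 at 1.53 (SE 0.101), RNF43 at 1.22 (SE 0.0996), MYC at 1.38 (SE 0.118) and NOTUM at 2.23 (SE 0.19). The counts adjusted over the list alone were the same 11 and 2, and the call was lost without the filter on low counts (0.0536), without control replicate 2 (0.0657), without METTL14 overexpression replicate 1 (0.0628) and with the length and GC trend removed (0.231).

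**Figure D4:**
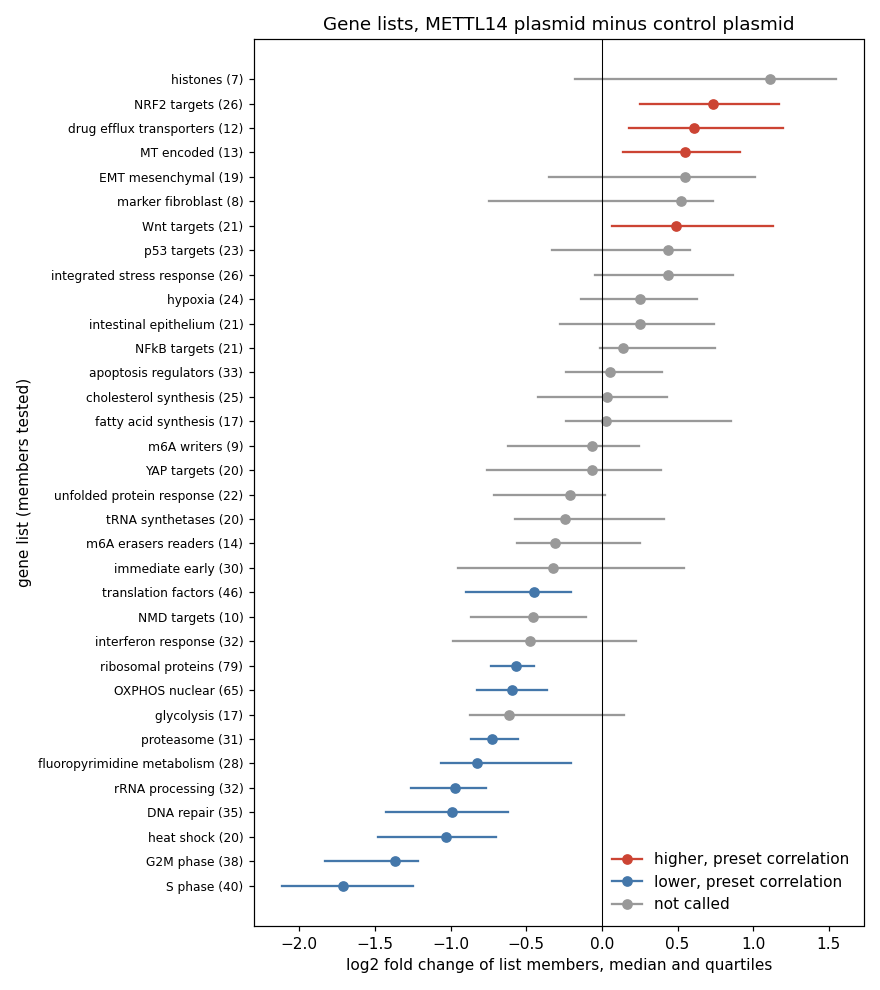
Median log2 fold change (point) and quartiles (line) of the members of each of the 34 tested gene lists, METTL14 plasmid minus control plasmid, with lists called by camera at its preset correlation in colour and the number of tested members in brackets. The S phase list has the lowest median (-1.71) and, of the called lists, the NRF2 targets the highest (0.73).

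The remaining lists were not called by camera in the test as planned, and many held members that moved in both directions. Of 26 genes of the integrated stress response 16 were higher and 5 lower (adjusted p = 0.0554), with CHAC1 at 2.41 (SE 0.194) and ATF5 at -1.94 (SE 0.281). Of 32 interferon response genes 16 were lower and 5 higher (0.0853), with ISG15 at -1.26 (SE 0.096) and STAT2 at 1.12 (SE 0.109), and of 17 glycolysis genes 9 were lower and 3 higher (0.0853), with ENO1 at -1.23 (SE 0.12). Of 24 hypoxia genes 9 were higher and 1 lower (0.11), with VEGFA at 1.96 (SE 0.23), of 19 mesenchymal genes 9 were higher and 3 lower (0.12), with MMP14 at 1.36 (SE 0.102), and of 21 intestinal epithelial genes 9 were higher and 4 lower (0.131), with CDH17 at 1.87 (SE 0.118). NF-kB targets had 5 of 21 higher (0.18), with NFKBIA at 1.12 (SE 0.141), and p53 targets 9 of 23 higher and 6 lower (0.35), with TP53INP1 at 3.45 (SE 0.319). Histone genes had 4 of 7 higher and 1 lower (0.181), genes of the unfolded protein response 2 of 22 higher and 9 lower (0.185), with CALR at -1.04 (SE 0.0931), and targets of nonsense-mediated decay 4 of 10 lower (0.185). The 7 histone genes are those of 41 that passed the filter, and 4 reached 1 CPM in each group. Without the filter on low counts the histone list of 31 genes leaned lower instead (camera adjusted p = 0.556). Readers and erasers of m6A had 4 of 14 higher, including the demethylase FTO (0.74, SE 0.111), and 6 lower, including HNRNPA2B1 (-1.38, SE 0.127; adjusted p = 0.244 for the list). Fatty acid synthesis (6 of 17 higher and 2 lower, 0.405), tRNA synthetases (7 of 20 and 9, 0.573), apoptosis regulators (6 of 33 and 5, 0.735), YAP targets (5 of 20 and 6, 0.835), cholesterol synthesis (7 of 25 and 8, 0.848) and immediate early genes (7 of 30 and 8, 0.863) were not called either, and the median (0.04) and mean (-0.003) of the cholesterol list differ in sign. Some of these lists were called by camera under alternatives: the integrated stress response as higher with limma-voom (adjusted p = 0.0228), a filter of 5 CPM (0.0334), replicate number as a term (0.0478) and without control replicate 2 (0.00433), and hypoxia and mesenchymal genes as higher with that filter (0.0219 and 0.0224). Called as lower were the unfolded protein response without control replicate 1 (0.00291), the interferon response without control replicate 1 (0.024) and without METTL14 overexpression replicate 2 (0.0296), and glycolysis with limma-voom (0.0495), without control replicate 2 (0.0485) and with the length and GC trend removed (0.0233). Immediate early genes were called lower without control replicate 1 (0.00659) and higher without control replicate 2 (0.0402). Fry, which tests whether a list's genes move one way and does not compare them with other genes, called 9 of these lists. It called NF-kB targets (adjusted p = 0.0377), hypoxia (0.0188), histones (0.0339), intestinal epithelium (0.017), mesenchymal genes (0.0176) and fatty acid synthesis (0.0263) higher, and m6A readers and erasers (0.0198), glycolysis (0.0445) and targets of nonsense-mediated decay (0.0422) lower.

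Markers of other cell types were few. At a mean of at least 1 CPM, 6 of 13 fibroblast markers were detected in each group, 3 of 13 leukocyte markers in the controls and 4 with METTL14, 1 and 2 of 10 endothelial markers, none of 8 erythroid markers and 2 of 12 neural markers in each group. COL6A1 (1.30, SE 0.111), CD68 (1.89, SE 0.112) and MAP2 (1.75, SE 0.219) were higher and CORO1A (-2.50, SE 0.232) and TUBB3 (-1.05, SE 0.113) lower. Of the 8 fibroblast markers tested, 3 were higher and 1 lower (camera adjusted p = 0.466, and adjusted p = 0.764 with an estimated correlation), COL1A1 (0.51, SE 0.179, adjusted p = 0.046) changing sign to -0.12 with the length and GC trend removed.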

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

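The alternatives with the trend on transcript length and GC content removed, with library totals only and without mitochondrial genes were chosen after the data were seen. METTL14 kept its direction and call in each alternative, with log2 fold changes between 3.73 and 4.04, and those without 1 library ran from 3.73 to 4.04 as well. The number of higher genes was 1416 and of lower genes 1357 with glmTreat against 1.5-fold, which asks for a larger change. It lay between 3104 and 3793 higher and 3172 and 3903 lower in the other alternatives that keep 4 libraries. Without 1 library, from 2306 to 4450 genes were higher and from 2305 to 4575 lower. There the lone library is assumed to vary like the other group, and the fits without a control, which called more genes, take their spread from the 2 closely matching METTL14 libraries. With the length and GC trend removed, 5613 of the 6998 reported calls were made again, 8 of them in the other direction. The calls that the other alternatives shared with the reported ones kept their direction. This is little support, since all fits use the same counts. Fits without 1 METTL14 library lost many of the reported calls. The labels do not say that a number marks a shared experiment, and the correlation of deviations between libraries with the same number, 0.044 over all tested genes and 0.286 over the more expressed ones, does not settle it with 2 libraries per group. A replicate block gave 3793 higher and 3903 lower genes, 5 higher and 10 lower lists, and a METTL14 log2 fold change of 3.88. Higher lists numbered 7 with the filter of 5 CPM, 2 with the length and GC trend removed, 0 with an estimated correlation and 10 with fry, and lower lists 0 with an estimated correlation and 13 with fry. The cause was not tested for the filter. The estimated correlation missed the planted list of the simulation, whose genes were drawn independently, which cannot show whether it misses the correlated lists here. Without 1 library, from 3 to 4 lists were higher and from 10 to 13 lower. Of 2512 values for 169 other named genes, 2447 kept direction and call, 57 lost the call, 7 gained one and 1 reversed, COL1A1 at -0.12 with the length and GC trend removed, where the cause was not tested. Most of the 169 genes were picked for large changes or small p-values in the same libraries, so the share of calls kept does not speak for other genes. Fits on FPKM were not run, since FPKM is not used here, and the non-robust fit does not enter the list tests. Few counts leave wide counting intervals, such as 19.9 to 4500 for ENOX1. Of simulated 1.5-fold changes 50% were found, which was not split by count level.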

Other observations

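The lists in this part other than the intestinal epithelial one, the NFAT5, EPCAM and same-symbol tests, the random lists for readthrough rows and the removal of the length and GC trend were chosen after the data were seen. Lysosomal genes rose with METTL14: 18 of 30 were higher, 2 lower and 10 not called (camera adjusted p = 0.000688, and adjusted p = 0.349 with an estimated correlation), with CTSB, cathepsin B, at 1.35 (SE 0.101), TPP1 at 1.23 (SE 0.103) and PSAP, prosaposin, at 1.18 (SE 0.12), and with MCOLN1 at -1.54 (SE 0.221). Metallothionein genes, which encode small metal-binding proteins, fell: 4 of 5 were lower (adjusted p = 0.0102, and adjusted p = 0.349 with an estimated correlation), with MT2A at 360 ± 124 CPM in the controls and 69.4 ± 6.38 with METTL14 (SD, n = 2). Their estimated correlation was 0.836, far above the preset value. Of 49 genes for proteins of the large subunit of the mitochondrial ribosome 42 were lower and none higher (1.46e-10, and adjusted p = 0.177 with an estimated correlation), with MRPL20 at -1.68 (SE 0.106), and MRPS6 of the small subunit, which the list does not cover, was higher (1.75, SE 0.104). MRPS6 shares exons with SLC5A3, which rose more (4.41), so a part of its rise from SLC5A3 reads cannot be told apart. Of 33 SR and hnRNP splicing factor genes 29 were lower and none higher (1.1e-09, and adjusted p = 0.177 with an estimated correlation). The iron storage genes FTH1 (6421 ± 177 against 2800 ± 119 CPM) and FTL (7112 ± 124 against 3324 ± 403 CPM) were both higher.

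Ribosomal protein, nuclear respiratory chain and proteasome genes and genes of S phase and G2 and mitosis were lower together. Fold change followed transcript length (Spearman's rho 0.17 across genes, which are not independent replicates) and GC content (0.207), but with that trend removed the median log2 fold change moved only from -0.61 to -0.47 for the 175 genes of the first 3 lists and from -1.63 to -1.48 for the 78 cell cycle genes, which argues against the trend as the whole cause. EPCAM, an epithelial surface gene, stood at -0.008 (SE 0.035 from the libraries), and at 0.18 with the trend removed, far from what dilution by cells without EPCAM would need. This is 1 gene, and other intestinal epithelial genes moved apart: of 21, 9 were higher and 4 lower, with KRT18 at -0.92 (SE 0.224), KRT8 at -0.90 (SE 0.195), KRT19 at -0.39 (SE 0.124) and CDH17 at 1.87 (SE 0.118), also picked after their values were seen. Dilution would lower them alike, but cells of another epithelial type stay open. A slower cell cycle with METTL14 may account for the lower lists, but cell number and phase are not analysed here, and a different response to cycloheximide or to the plasmids stays open and untested.

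SLC6A12 (log2 fold change 6.30) and SLC5A3, a myo-inositol transporter named after its values were seen (4.41), carry osmolytes into cells and are targets of NFAT5, the regulator of the response to high osmolarity. Of 14 NFAT5 list genes 10 were higher and 2 lower (camera adjusted p = 0.0101, and adjusted p = 0.177 with an estimated correlation), with AKR1B1 at 1.52, SLC6A6 at 1.04, HSPA4L at -1.17 and S100A4 at -0.80. Without both transporters the median of the other 12 genes was 0.99, at percentile 100 of 10000 random lists of like expression (95% of these between -0.52 and 0.46), so a response through NFAT5 may explain the pattern, as a hypothesis found and tested on the same data. SLC5A3 shares exons with MRPS6, which was higher too (1.75), less than SLC5A3 but more than the bound of 1 set for excluding the overlap, so for SLC5A3 a part from MRPS6 reads cannot be told apart from its own rise. The reverse, SLC5A3 reads counted for MRPS6, was not tested. SLC6A12 has no such overlap, and a difference in medium between the groups was not tested.

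Rows annotated as readthrough transcripts, which join neighbouring genes, held some of the largest rises, and 9 of 228 had no count in either control while none was without counts in both METTL14 libraries. As a set their median did not shift: 48 were higher, 33 lower, and their median log2 fold change of 0.05 lay within the 0.02 to 0.33 of random lists of like expression, near the lower end. Their log2 fold changes were more spread out (SD 1.933, against 0.952 for other tested rows), which the median does not measure. The other rows were not matched in expression here, so these SDs do not show whether the wider spread is particular to readthrough rows. Background reads such as genomic DNA were tested, by a prediction set before the result was seen, on olfactory receptor genes, whose mean share of counts was 2.13 times as high with METTL14. The lowest ratio between libraries was 1.99, just under the bound of 2 that would have favoured background and well above the 1.5 that would have excluded it, and although OR2A7 and OR2W3 hold most of these counts, the other receptor rows also had 98 counts against 37, and 905 gene rows had counts only with METTL14 against 598 only in the controls, so a low background cannot be told apart from a rise of weakly expressed genes. A rise of the primary gene alone stays open: over the 130 readthrough rows with another row of their symbol, the median difference in log2 fold change between both rows was 0.094 (95% bootstrap interval -0.08 to 0.31), around the bound of 0.2 set for it.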
